A study of Arabidopsis thaliana with 6 samples.

How the data were processed

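Total RNA from cotyledons of Arabidopsis thaliana (ecotype Col-0) was hybridised, 1 sample per array, to 1-colour Affymetrix arrays after biotin labelling by in vitro transcription, per the labels' protocols. Plants of 3 genotypes had been grown for 4 days on medium with 100 mM sucrose: the wild type, sicy-192 and the double mutant sicy-192 gun1-101. All had 16 h of light (100 µmol per square metre and second, 25 °C) and 8 h of dark (22 °C). Each genotype has 2 arrays, which the labels call biological replicates. Nothing further says whether the plants of each replicate were raised separately, so p-values measure the spread between these samples. The labels do not name the primer of the reverse transcription, on which the copied share of RNAs without a long poly(A) tail, such as plastid and ribosomal RNAs, depends.

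The deposited values are linear signal intensities, 1 per probe set, and no header names the algorithm that made them. GCOS is named in the submitters' processing notes, without a version. Every deposited column has a trimmed mean of 500 (2% trimmed at each end), found from the values, so the arrays had been scaled to a common level before deposit. No detection calls were used here. The table has 22810 rows, of which 64 are control probe sets. Of the other 22746 probe sets, the gene table used here gives 13513 a single gene, 503 several genes and 8730 none. Of the probe sets with a single gene, 13436 matched a locus of the RefSeq table through the Entrez identifier. That table gave the symbols, the loci used to assign genes to lists, and the chromosome that marks plastid-encoded genes. A probe set without a listed gene is unnamed here, and probe sets with several genes were not named. No genome build is stated, so no coordinates are given.

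Each array was rescaled to a trimmed mean of 500, 16 was added, and log2 was taken. Fold changes are therefore on the log2(signal + 16) scale, which understates the change of dim probe sets. The 14785 probe sets whose mean log2 value over the 6 arrays was above the 35th percentile were tested, and 7961 dimmer ones were left out. The tested probe sets hold 8033 distinct named genes, each represented by its brightest probe set where a gene is named or counted in a list. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with all 6 arrays in 1 fit, so that the 3 groups of 2 shared 1 estimate of the spread. The fit had 3 residual and 6.27 prior degrees of freedom. Benjamini-Hochberg adjustment was over the probe sets tested, and a probe set was called changed at an adjusted p under 0.05. Signals are given as mean ± SD of the 2 rescaled arrays (n = 2), and log2 changes with the standard error of the fit. On simulated data for sicy-192 against wild type with the 14785 probe sets and 6 arrays, the fit recovered 81% of 100 changes of 1 and 99% of 100 changes of 2 on the log2 scale, and 8.63% of its calls were false. The simulation was a single draw of independent normal noise, without a replicate effect and with fewer changed probe sets than were called in the data. The rates for the real arrays may therefore differ. As a count that needs no model, probe sets at least 2-fold apart in all pairings of an array of one group with an array of the other were also counted.

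Before the data were examined, 27 gene lists were fixed, along with the comparisons, the rule for named genes and the alternatives. Only 7 of these lists had 5 or more tested genes, since the gene table names few of their members. A further 17 lists, 13 of them with 5 or more tested genes, were added after the names in the gene table had been seen and before any groups were compared. Lists of 5 or more were tested with camera (preset inter-gene correlation 0.01, two-sided), adjusted over the 7 and over the 13 lists separately. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, were run as alternatives. For each of sicy-192 against wild type and the double mutant against sicy-192, the rule names the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups do not overlap. For the double mutant against wild type it names 5 and 5, and from each list up to 4 members with the largest change.

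The other alternatives were offsets of 1 and 64, no filter and a filter at the 50th percentile, quantile normalization, the values as deposited, centring each array on its median, no variance trend, only the arrays of the 2 groups compared, the replicate number as a block, a threshold of 0.10, and leaving out each array in turn. Comparisons that share arrays were set beside 100 simulations of unchanged groups. Without a gun1-101 single mutant in the design, the effect of gun1-101 in the wild-type background is not analysed here and no interaction can be tested. GUN1 (AT2G31400) and the plastid invertase gene INV-E (AT5G22510) have 0 probe sets named in the gene table, so the genotypes were not checked from the arrays.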

Results

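The arrays compared cotyledons of 3 genotypes on a sucrose-rich medium. The sicy-192 line (sugar-inducible cotyledon yellow) is known for a gain-of-function mutation in a plastid invertase, and GUN1 is a pentatricopeptide repeat protein of the plastid that acts in signalling from plastid to nucleus. The first comparison asks what the sicy-192 mutation changes, the second which of its changes differ when GUN1 is also mutated, and the third what separates the double mutant from the wild type. Replicates correlated at r = 0.980 in wild type, 0.979 in sicy-192 and 0.983 in the double mutant, across the 14785 tested probe sets, which are not independent of each other. The first principal component held 48.3% of the variance and the second 33.6%, and both separated the genotypes, while the third (10.8%) separated replicate 1 from replicate 2 in all 3 groups. The bioB spike, a bacterial RNA added as a control, split the arrays the same way, with a signal of 313 to 391 for its 3' probe set in the replicate 1 arrays and 51.6 to 68.8 in the replicate 2 arrays. Changes computed from the replicate 1 arrays alone and from the replicate 2 arrays alone correlated across probe sets at r = 0.828 for sicy-192 against wild type, 0.814 for the double mutant against sicy-192 and 0.845 for the double mutant against wild type. Precision is limited by the number of arrays.

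Nuclear genes for photosynthesis were lower in sicy-192 than in wild type. Phosphoribulokinase (PRK), a Calvin cycle enzyme, had a signal of 20249 ± 3521 in wild type and 3332 ± 516 in sicy-192 (SD, n = 2 each), a log2 change of -2.60 ± 0.17 (SE, adjusted p = 3.34e-05 in limma). The 4 tested Calvin cycle genes all fell, the others being the phosphoglycerate kinase gene AT1G56190 (-2.48), SBPASE (-1.90) and the Rubisco activase RCA (-1.01). The call of RCA was lost under 3 alternatives, with an adjusted p up to 0.12. So did the 3 tested antenna genes, LHCB4.3 (3873 ± 64.2 to 657 ± 99.7, log2 change -2.54, adjusted p = 2.03e-05), LHCB4.2 (-2.16) and LHCB4.1 (-1.41). All 6 tested genes of photosystem and electron transport subunits fell, also when adjusted over the list alone, led by PSB27 (-2.03), PSBY (-1.93) and PSAN (-1.75). Their median change was -1.64, and camera gave an adjusted p of 9.61e-09, against an adjusted p = 0.149 with an estimated correlation. Of 9 tetrapyrrole and chlorophyll synthesis genes, 8 fell (8 adjusted over the list alone), among them the protochlorophyllide reductase PORB (6173 ± 1554 to 882 ± 244, log2 change -2.79), HEME1 (-1.71) and CHLM (-1.54). HEMA2, named after its values were seen, did not pass (-0.03, adjusted p = 0.911). The median of this list was -0.96 (camera adjusted p = 2.22e-08, and adjusted p = 0.0876 with an estimated correlation). All 9 nuclear genes of plastid ribosomal proteins fell (9 adjusted over the list alone), led by AT1G29070 (-1.13) and AT5G47190 (-0.92; call lost without sicy-192 replicate 1, adjusted p = 0.0591), with a median of -0.77 (camera adjusted p = 6.53e-08, and adjusted p = 0.102 with an estimated correlation). This median was -0.43 with quantile normalization.

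Plastid-encoded transcripts of photosynthesis were also lower in sicy-192. The photosystem II gene psbC fell from 6644 ± 1352 to 693 ± 222 (log2 change -3.25 ± 0.23, adjusted p = 4.58e-05), psbH from 2328 ± 229 to 158 ± 6.37 (-3.75), and rbcL, for the large subunit of Rubisco, from 5014 ± 144 to 854 ± 345 (-2.59). Of the 14 tested plastid-encoded photosynthesis genes, 10 fell (12 adjusted over the list alone), with a median of -1.91 (camera adjusted p = 6.43e-12; adjusted p = 0.0876 with an estimated correlation). Not passing were atpA (-0.03), atpB (-0.38), petD (-0.85) and ndhA (-0.88; these 4 were named after their values were seen). The 6 tested plastid genes outside photosynthesis had a median of 0.13 (camera adjusted p = 0.752), which was 0.55 with quantile normalization and -0.04 after centring the arrays on their medians. Of these 2 were called higher and 1 lower (the same adjusted over the list alone). The RNA polymerase genes rpoC2 (1332 ± 160.0 to 3591 ± 481, log2 change 1.42, adjusted p = 0.000555) and rpoC1 (1.11) rose and rpoA, named after its values were seen, did not pass (0.08). In the same list accD, for a subunit of acetyl-CoA carboxylase, fell (-1.43). The added lists of plastid-encoded photosystem and NDH genes share genes with the list of 14, so they are not separate support. In the added lists, 14 of 19 plastid-encoded photosystem genes fell and 1 rose (median -1.55, camera adjusted p = 5.12e-12, and adjusted p = 0.167 with an estimated correlation). The gene that rose was psbN (89.0 ± 36.7 to 843 ± 437, log2 change 2.98 ± 0.44, adjusted p = 0.00156), which lies on the opposite strand within the psbB operon. Of 9 plastid NDH genes 6 fell (median -0.88, camera adjusted p = 1.16e-05, and adjusted p = 0.187 with an estimated correlation). Of 15 plastid-encoded ribosomal protein genes 4 fell: rpl33 (-2.63), rps18 (-1.42), rpl22 (-1.03) and rps4 (-0.76). The calls of rpl22 and rps4 were lost with quantile normalization (adjusted p = 0.117 and 0.175), without the filter (0.0834 and 0.0669) and without some of the arrays (up to 0.115 and 0.156). The median of that list was -0.42 (camera adjusted p = 0.0249, and adjusted p = 0.591 with an estimated correlation). The call was lost with quantile normalization (adjusted p = 0.435, median -0.15), with the 50th percentile filter (0.0522), without wild-type replicate 2 (0.117), without sicy-192 replicate 2 (0.128) and with fry (0.463). Within replicate 1 and within replicate 2 arrays, the photosystem genes' median was -1.47 and -1.50, and that of the ribosomal protein genes -0.20 and -0.51.

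Genes of anthocyanin synthesis were higher in sicy-192. All 6 tested members rose (6 adjusted over the list alone), with UF3GT going from 1002 ± 165 to 3879 ± 103 (log2 change 1.95 ± 0.15, adjusted p = 6.12e-05), DFR, the dihydroflavonol reductase, rising by 1.60, AT5MAT by 1.57 and AT4G14090 by 1.39. The call of AT5MAT was lost without sicy-192 replicate 2 (adjusted p = 0.0534). The median was 1.48 (camera adjusted p = 2.34e-05, and adjusted p = 0.225 with an estimated correlation). Isocitrate lyase (ICL), an enzyme of storage oil mobilisation, rose from 1669 ± 457 to 10699.5 ± 101 (log2 change 2.70 ± 0.19, adjusted p = 4.58e-05). Of the 5 starch genes, APL3, a large subunit of ADP-glucose pyrophosphorylase, rose (1.07) and SBE2.2 fell (-0.49; 1 up and 2 down adjusted over the list alone), and the list was not called (camera adjusted p = 0.432). The call of SBE2.2 was lost under 5 alternatives (adjusted p up to 0.141) and that of APL3 without wild-type replicate 1 (adjusted p = 0.0518). Of 4 tested genes from the list of sugar-repressed genes, AT3G15450 fell (-2.09) and PPDK rose (1.08). Of 72 cytosolic ribosomal protein genes 1 was called lower (median -0.13, camera adjusted p = 0.00108, and adjusted p = 0.591 with an estimated correlation), and the median turned to 0.16 with quantile normalization. The list's call was lost without wild-type replicate 2 (adjusted p = 0.294), without sicy-192 replicate 1 (0.0509) and with fry (0.463).

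The 10 largest rises in sicy-192 were led by AT1G17960 (39.7 ± 38.8 to 1809 ± 56.7, log2 change 5.23 ± 0.39), the MATE family transporter AT2G04050 (4.35), the small heat shock protein gene AT5G51440 (4.27) and AT2G21640 (269 ± 111 to 4814 ± 14, log2 change 4.14, adjusted p = 1.96e-05). AT2G47780 (3.92), AT5G60250 (3.79), chr31 (3.68), AT3G61090 (3.51), AT4G25330 (3.43) and AT4G22960 (3.21) followed. The wild-type signals of chr31 (13.8 ± 15.6), AT3G61090 (13.3 ± 13.4) and AT4G25330 (18.4 ± 17.9) were near the added 16, so the sizes of their changes depend on it. Besides psbH and psbC, the 10 largest falls were AT1G13650 (-3.53), AT1G70820 (-3.42), AT3G62550 (-3.38), AT3G28220 (-3.33), AT1G75460 (-3.32), AT3G28270 (-3.32), AT5G48490 (-3.26) and the sucrose phosphate synthase gene ATSPS4F (-3.14). In all, 3402 of 14785 probe sets changed, 2041 higher and 1361 lower, against 5460 at an unadjusted p under 0.05. Of the called probe sets 548 were at least 2-fold higher and 692 at least 2-fold lower. In every pairing of arrays, 723 probe sets were at least 2-fold apart. When the same 4 arrays were regrouped so that each side held an array of both genotypes, the counts were 23 (split by replicate number) and 0 (crossed). A probe set that differs between genotypes can hardly pass such a regrouping, so these counts do not estimate chance pairings in any comparison. The median of all tested probe sets was 0.16 in this comparison, so list medians relative to it are 0.16 lower than given (-1.80 for photosystem subunits, 1.32 for anthocyanin synthesis). The share of calls that were higher, 60%, was 48.1% with quantile normalization and 35.4% after centring on the median. The count was 2218 without wild-type replicate 1, 2094 without sicy-192 replicate 1 and 2043 without sicy-192 replicate 2. That of 2-fold pairings was 1153 without wild-type replicate 2.

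**Figure D1:**
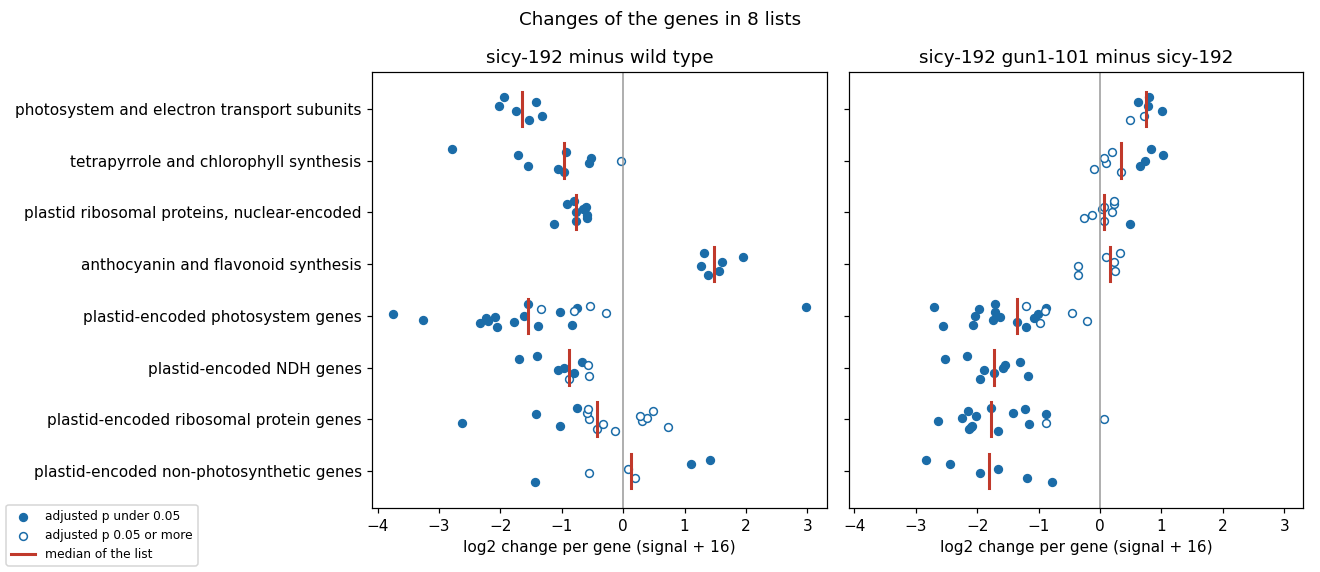
Log2 change (log2 of signal + 16) of each tested gene in 8 lists, sicy-192 minus wild type on the left and sicy-192 gun1-101 minus sicy-192 on the right; each point is a gene, filled where the adjusted p was under 0.05, and the red line is the list's median. The nuclear photosystem genes lie below 0 on the left (median -1.64) and above 0 on the right (0.75), and the plastid-encoded photosystem genes have medians of -1.55 and -1.35.

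In the double mutant, nuclear photosynthesis genes were higher than in sicy-192 and plastid-encoded transcripts were lower. LHCB4.3 rose from 657 ± 99.7 in sicy-192 to 2397 ± 119.6 in the double mutant (SD, n = 2 each; log2 change 1.85 ± 0.15, SE, adjusted p = 0.000128 in limma), and LHCB4.2 (1.12) and LHCB4.1 (0.77) rose too. Of the 4 Calvin cycle genes, AT1G56190 (1.89), PRK (3332 ± 516 to 8733 ± 351, log2 change 1.39) and SBPASE (1.02) rose, and RCA had a change of 0.54 (adjusted p = 0.16). Of the 6 photosystem and electron transport genes 4 rose (6 adjusted over the list alone), among them PSAN (1.0) and PSBY (0.80), with a median of 0.75 (camera adjusted p = 3e-04, and adjusted p = 0.353 with an estimated correlation; fry adjusted p = 0.0526). Of 9 tetrapyrrole genes 4 rose (4 adjusted over the list alone), HEME1 (1.03), PORB (0.83), HEMA2 (0.73) and CHLM (0.65), with a median of 0.34 (camera adjusted p = 0.00746, and adjusted p = 0.302 with an estimated correlation). The calls of LHCB4.1, PSBY, PSB27, PSBW, PORB, CHLM and HEMA2 were each lost without at least 1 of the arrays compared or under another alternative. Their highest adjusted p there were 0.159 for LHCB4.1, 0.0893 for PSBY, 0.0593 for PSB27, 0.0915 for PSBW (lost without any 1 of the 4 arrays), 0.158 for PORB, 0.162 for CHLM and 0.138 for HEMA2. Of the 9 nuclear genes of plastid ribosomal proteins 1 rose, AT1G29070 (0.49; 0 adjusted over the list alone), a call lost without any 1 of the 4 arrays compared. The list was not called (camera adjusted p = 0.346). None of the 6 anthocyanin genes was called by limma at the adjusted threshold or adjusted over the list alone (median 0.17, camera adjusted p = 0.645, fry adjusted p = 0.847).

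Of the 66 tested probe sets of plastid-encoded genes, 56 fell from sicy-192 to the double mutant and 0 rose. Between the same arrays the control probe set for 25S ribosomal RNA, which was not among those tested, went from 1275 ± 145 to 8070 ± 413. Among the 14 photosynthesis genes 12 fell (12 adjusted over the list alone), with a median of -1.49 (camera adjusted p = 1.18e-08, and adjusted p = 0.119 with an estimated correlation). The photosystem I gene psaB fell from 7165 ± 2393 to 1185 ± 223 (log2 change -2.55 ± 0.26, adjusted p = 0.000372), as did petA (-2.19), atpA (-2.06) and atpB (-2.02), with the call of atpA lost without double mutant replicate 2 (adjusted p = 0.0508). All 6 genes outside photosynthesis fell (6 adjusted over the list alone), with a median of -1.81 (camera adjusted p = 1.64e-06, and adjusted p = 0.119 with an estimated correlation). They included rpoC2 (3591 ± 481 to 493 ± 89.8, log2 change -2.83 ± 0.18, adjusted p = 7.14e-05), rpoC1 (-2.44), matK (-1.95) and rpoA (-1.66). In the added lists, 14 of 19 photosystem genes (median -1.35), 9 of 9 NDH genes (-1.73) and 13 of 15 ribosomal protein genes (-1.78) fell. Their camera adjusted p were 1.37e-09, 4.95e-08 and 1.37e-09, and with an estimated correlation adjusted p = 0.117, 0.117 and 0.206. psbN, which had risen in sicy-192, fell (-2.70). Within replicate 1 and within replicate 2 arrays, the median of the ribosomal protein genes was -2.17 and -1.39.

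COR15A and COR15B were among the largest rises from sicy-192 to the double mutant. COR15A, a cold-regulated protein of the chloroplast stroma, went from 112 ± 88.6 to 1619 ± 1045 (log2 change 3.71 ± 0.53, adjusted p = 0.00164), and COR15B from 35.6 ± 15.2 to 428 ± 71.9 (3.13). COR47, the third tested member of the cold and drought list, which is too short for a list test, had a change of 0.54 (adjusted p = 0.201). AT1G53540 (28.4 ± 21.9 to 833 ± 725, log2 change 4.02 ± 0.57) and ATHSP22.0 (2.53), the 2 tested genes of the heat shock list, rose. The call of ATHSP22.0 was lost without sicy-192 replicate 2 (log2 change 1.84, adjusted p = 0.0958) and without the filter (adjusted p = 0.063). The other largest rises were AT3G28270 (4.27), AT3G51750 (3.43), AT1G72900 (3.33), AT5G42760 (3.28), AT4G25170 (2.94), AT2G29500 (2.89) and the glycosyltransferase gene UGT84A3 (2.89). Besides rpoC2 and psbN, the largest falls were AT4G25330 (-3.11), AT3G61090 (-3.07), AT1G67860 (-2.98), AT4G17470 (-2.95), chr31 (-2.92), AT1G20120 (-2.90), AT4G29700 (-2.79) and AT4G29690 (-2.66). Of 24 UDP-glycosyltransferase genes 8 rose and 2 fell (median 0.29, camera adjusted p = 0.0125, and adjusted p = 0.17 with an estimated correlation). Of 13 serine carboxypeptidase-like genes 5 fell (median -0.60, camera adjusted p = 0.00142, and adjusted p = 0.146 with an estimated correlation). Of 13 expansin and XTH genes, which act on the cell wall, 4 fell (median -0.46, camera adjusted p = 0.0491, and adjusted p = 0.206 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.056), without the variance trend (0.0512), without wild-type replicate 2 (0.0607), without sicy-192 replicate 2 (0.0727) and without double mutant replicate 1 (0.16). Of the 5 starch genes 2 fell, APL3 (-1.0) and DPE1 (-0.53; 2 adjusted over the list alone). Both calls were lost under some alternatives (adjusted p up to 0.125 and 0.129), and the list was not called (camera adjusted p = 0.08).

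In all, 3060 probe sets changed between sicy-192 and the double mutant, 1410 higher and 1650 lower, against 5083 at an unadjusted p under 0.05. Of the called probe sets 606 were at least 2-fold higher and 546 at least 2-fold lower. In every pairing of arrays 646 probe sets were at least 2-fold apart, against 24 and 1 in such regroupings. The count was 1713 without sicy-192 replicate 1, 1997 without sicy-192 replicate 2, 1710 without double mutant replicate 1 and 1457 without double mutant replicate 2. That of 2-fold pairings was 1048 without sicy-192 replicate 2 and 977 without double mutant replicate 1.

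**Figure D2:**
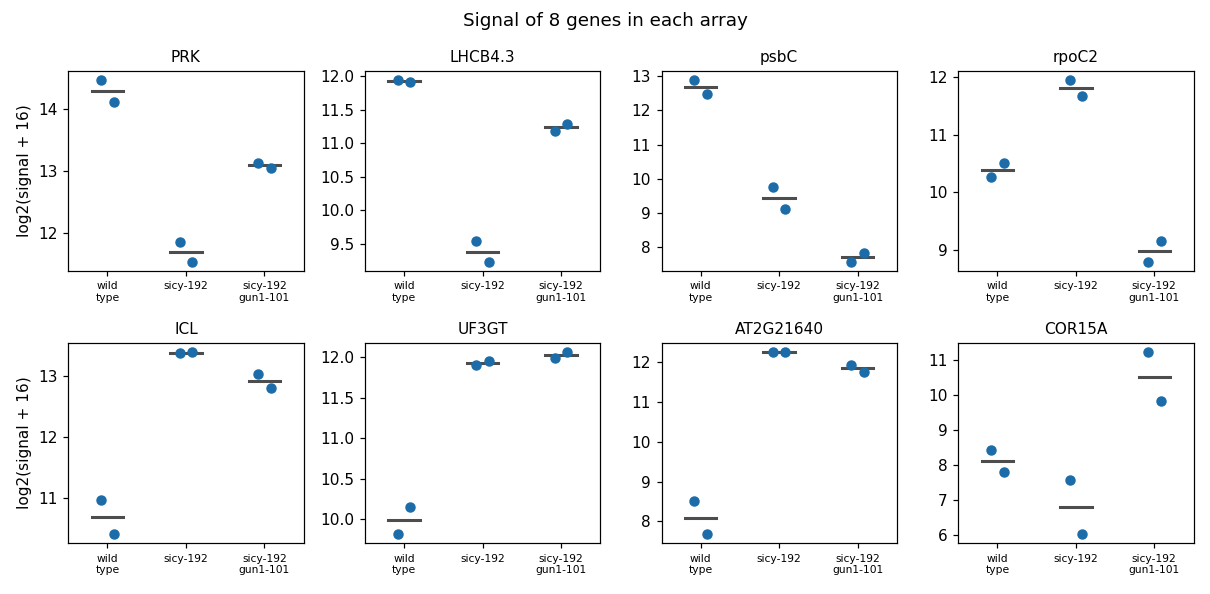
Log2(signal + 16) of 8 named genes in each of the 6 arrays; points are arrays (n = 2 per genotype), bars are group means, and each panel has its own vertical scale, which does not start at 0. PRK and LHCB4.3 lie lowest in sicy-192, psbC lies lowest in the double mutant, and rpoC2 lies highest in sicy-192.

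Of the 1361 probe sets lower in sicy-192 than in wild type, 606 (44.5%) rose from sicy-192 to the double mutant, and of the 2041 higher ones 484 (23.7%) fell. Together 1090 probe sets (32%) changed back, and 746 of these (68.4%) were no longer called against wild type. The shares of lower and higher probe sets are not like for like. At least 2-fold were 692 of the lower but only 548 of the higher ones, and a smaller change leaves less to call back. Counted at any size of the second change, 80.1% of the lower and 68.8% of the higher ones went the opposite way. The split into lower and higher also depended on the scaling, as given above. The nuclear genes LHCB4.3, PRK, SBPASE, PSAN, HEME1 and PORB were among those that fell and rose, and chr31, AT3G61090, AT4G25330, rpoC2 and psbN among those that rose and fell. In the same direction in both steps went 115 higher probe sets and 69 lower ones, psbC, psbH and psaB among the lower. Independent lists of these sizes would share 129.8 (lower, then higher) and 227.8 (higher, then lower). Both comparisons use the sicy-192 arrays, which alone gives opposite signs. Across probe sets the 2 changes correlated at r = -0.358, against -0.5 in simulated unchanged groups, with a covariance of -0.133 against -0.0236. The simulated r follows from groups of equal size that share arrays, so setting the 2 r side by side does not measure how much went back. The simulation gave arrays with the same replicate number nothing in common. How much of the excess over independent lists the shared arrays give was not estimated. The count was 588 without sicy-192 replicate 1, 643 without sicy-192 replicate 2, 661 without double mutant replicate 1 and 568 without double mutant replicate 2.

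**Figure D3:**
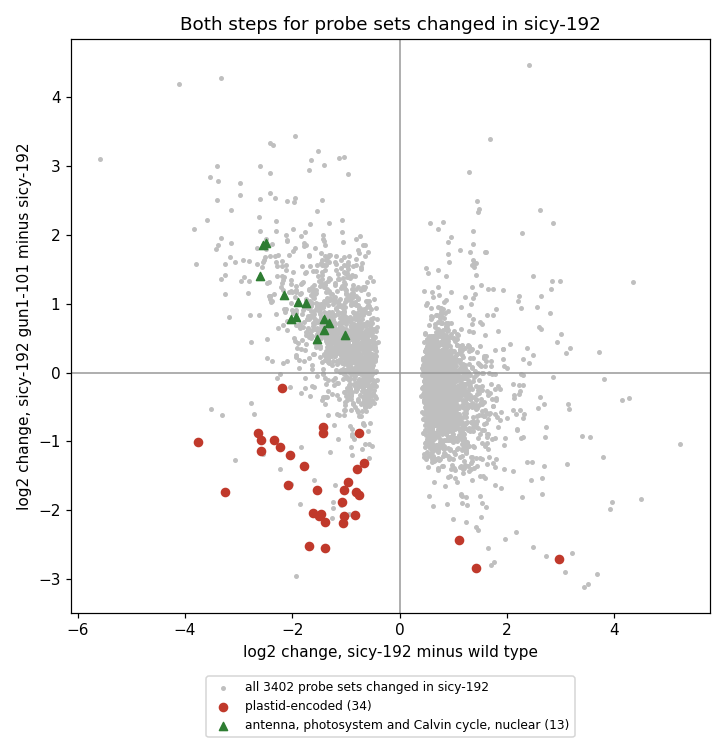
Log2 change from wild type to sicy-192 (horizontal) and from sicy-192 to sicy-192 gun1-101 (vertical) for the 3402 probe sets changed in sicy-192; each point is a probe set, and the sicy-192 arrays enter both axes with opposite sign, which alone tilts the cloud downwards to the right. All 13 nuclear antenna, photosystem and Calvin cycle genes (triangles) lie above 0 on the vertical axis, and all 34 probe sets of plastid-encoded genes (red) lie below 0.

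Against wild type, plastid-encoded transcripts were lower in the double mutant. The nuclear lists of photosystem subunits, tetrapyrrole synthesis and plastid ribosomal proteins were still lower. All 14 plastid-encoded photosynthesis genes fell (14 adjusted over the list alone), with a median of -3.24 (camera adjusted p = 9.34e-17, and adjusted p = 0.0562 with an estimated correlation), with psbC going from 6644 ± 1352 to 192.1 ± 25.3 (SD, n = 2 each; log2 change -4.99, adjusted p = 6e-06 in limma). All 6 plastid genes outside photosynthesis fell too (6 adjusted over the list alone; median -1.50, camera adjusted p = 1.96e-06, and adjusted p = 0.121 with an estimated correlation). Of the nuclear genes, 5 of 6 photosystem and electron transport genes (6 adjusted over the list alone; median -0.92, camera adjusted p = 7.03e-05, and adjusted p = 0.213 with an estimated correlation) fell. So did 9 of 9 plastid ribosomal protein genes (9 adjusted over the list alone; median -0.63, camera adjusted p = 1.58e-05, and adjusted p = 0.124 with an estimated correlation). With quantile normalization these 2 medians were -0.57 and -0.42. The antenna gene LHCB4.1 (-0.64) was at -0.12 there (adjusted p = 0.5 in limma). Its call was also lost without the filter (adjusted p = 0.123) and without the variance trend (0.0679). The call of the Calvin cycle gene AT1G56190 was lost with quantile normalization too (-0.40, adjusted p = 0.0546). Of 9 tetrapyrrole genes 8 fell and HEMA2 rose (0.70), with the same counts adjusted over the list alone (median -0.68, camera adjusted p = 0.000153, and adjusted p = 0.124 with an estimated correlation). All 6 anthocyanin genes remained higher than in wild type (6 adjusted over the list alone; median 1.72, camera adjusted p = 4.04e-05, and adjusted p = 0.213 with an estimated correlation). So did ICL (7796 ± 855, log2 change 2.24). Of the 5 starch genes DPE1 (-0.93) and SBE2.2 (-0.66) fell (2 adjusted over the list alone; median -0.61, camera adjusted p = 0.0382, and adjusted p = 0.223 with an estimated correlation). The list's call was lost without wild-type replicate 2 (adjusted p = 0.253, median -0.21), without double mutant replicate 2 (0.057) and with fry (0.051), and that of SBE2.2 without double mutant replicate 1 (0.056). Of the added lists, 16 of 19 plastid-encoded photosystem genes (median -3.25), 9 of 9 NDH genes (-2.54) and 14 of 15 ribosomal protein genes (-1.86) fell. Their camera adjusted p were 5.15e-17, 5.74e-11 and 1.17e-12, and adjusted p = 0.0729, 0.0729 and 0.233 with an estimated correlation. Of 6 mitochondrion-encoded genes 3 rose (median 0.77, camera adjusted p = 0.0446, and adjusted p = 0.422 with an estimated correlation). That call was lost without wild-type replicate 2 (adjusted p = 0.0856), without double mutant replicate 1 (0.0779) and with fry (0.0591). Of 13 expansin and XTH genes 5 fell and 1 rose (median -0.52, camera adjusted p = 0.0446, and adjusted p = 0.233 with an estimated correlation). This call was lost after centring on the median (adjusted p = 0.0597), with the 50th percentile filter (0.0882, median -0.32), without wild-type replicate 2 (0.0856) and without double mutant replicate 1 (0.108).

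Among probe sets with 1 named gene, the largest rises against wild type were AT2G04050 (50.7 ± 16.1 to 3319 ± 16.7, log2 change 5.67 ± 0.29), AT2G23910 (4.98), UGT73C1 (4.3), AT1G17960 (4.19) and AT2G41730 (4.17). The largest falls were psbC, psbH (-4.75), AT5G20790 (-4.33), ndhJ (-4.21) and psaB (-3.94). The count of changed probe sets was 4450, 2560 higher and 1890 lower, against 6243 at an unadjusted p under 0.05. In all, 797 were at least 2-fold apart in every pairing, against 6 and 0 in such regroupings. The share of calls that were higher, 57.5%, was 38.6% after centring on the median. Without wild-type replicate 1 the count was 2925, without double mutant replicate 1 it was 2307 and without double mutant replicate 2 it was 2491, while that of 2-fold pairings was 1306 without wild-type replicate 2. With sicy-192 against wild type, 756 lower and 1107 higher probe sets were shared, where independent lists would share 174.0 and 353.4. The changes correlated at r = 0.594 across probe sets (0.501 in simulated unchanged groups), with a covariance of 0.257 (0.0237 simulated). Both comparisons use the wild-type arrays, which alone sets the simulated r.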

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

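The tests of the 25S ribosomal RNA probe set and of the second step of the plastid transcripts were chosen only after those results had been seen, and the other tests were written before the values they measure were computed but after the counts, the overlap of the comparisons and the genes with the largest changes were known.

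The control probe set for 25S ribosomal RNA, which is tested in no comparison of the report, stood above its wild-type level in the double mutant. Its signal was 452 and 1764 in the wild-type arrays (1108 ± 928), 1378 and 1173 in sicy-192 and 7778 and 8362 in the double mutant (8070 ± 413), a ratio of means of 7.29 between double mutant and wild type. Degraded RNA would raise the ratio of 3' to 5' probe sets. The double mutant's mean ratio divided by the wild type's was, however, at most 0.93 over actin, GAPDH and ubiquitin. The actin ratio was 6.1 to 7.2 in the replicate 1 arrays and 4.0 to 4.9 in the replicate 2 arrays. The group means do not show this split by replicate number. The spiked controls had a median log2 change of -0.25 from wild type to the double mutant. Every array had been scaled to a common level, which takes out a difference in brightness shared by the whole array. The spiked controls therefore cannot decide whether labelling or scanning was brighter in the double mutant, and no conclusion is drawn from them. A different carry-over of ribosomal RNA into the labelled pool and a difference between genotypes stay open, and the spread between the wild-type arrays limits both readings.

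Plastid-encoded photosystem transcripts fell in sicy-192, and 56 of 66 probe sets of plastid-encoded genes fell from sicy-192 to the double mutant. For the first step, scaling of the arrays is argued against among the scalings tried, since the photosystem median was still -1.35 under the one that brought it nearest to 0. No test of scaling was set for the second step, where this median was -1.25 with quantile normalization. Less plastid RNA of every kind is argued against for the first step, with a limit. The ribosomal protein genes' median lay 1.12 above the photosystem genes' (permutation p = 0.00234, 100000 permutations over genes, two-sided). The permutation takes genes as independent, while the correlation estimated among the ribosomal protein genes was 0.464, so this p is likely too small. The photosystem and ribosomal medians were -1.47 and -0.20 within replicate 1 arrays, and -1.50 and -0.51 within replicate 2 arrays. For the second step the same difference was -0.43 (permutation p = 0.34). That is past the bound of 0.3 set for equal falls and short of that set for unequal ones. The photosystem and ribosomal medians were -1.50 and -2.17 within replicate 1 arrays, and -1.29 and -1.39 within replicate 2 arrays. With quantile normalization they were -1.25 and -1.88. A general loss of plastid RNA and a selective one therefore cannot be told apart with these 19 and 15 genes. The genotypes stay open as a biological explanation of both steps, as does, untested, a different make-up of the labelled RNA for the second, where the 25S signal went from 1275 to 8070.

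Changes of sicy-192 went back in the double mutant more often than independent lists would. The shared sicy-192 arrays alone give opposite signs by chance, so the sicy-192 change was taken from one replicate number and the double mutant's change from the other. Of the 1000 largest sicy-192 changes, 76.7% went the opposite way when found in replicate 1 and 73.8% when found in replicate 2. This argues against noise of single shared arrays as the whole cause. A difference other than genotype that is common to both sicy-192 samples would give opposite signs in this split too, and stays open. A hypothesis that the gun1-101 mutation reverses part of the response fits these shares, and without a gun1-101 single mutant an independent effect of gun1-101 in the opposite direction stays open.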

How the results depend on the processing

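The tests of the 13 added lists were chosen after the names in the gene table had been seen and before any comparison, and no test in this part was added after its result was seen. Of 4544 values of named genes under the alternatives, 4283 kept their call, 261 lost it and 0 reversed. Of 588 values of called lists, 532 kept the call, 55 lost it and 1 reversed: the median of cytosolic ribosomal proteins in sicy-192 against wild type, 0.16 with quantile normalization. With an estimated correlation, camera called 0 of the 7 fixed lists in each comparison (5, 4 and 7 with the preset value), where each correlation rests on 3 residual degrees of freedom. The values as deposited hardly differ from the rescaled ones, so that alternative tests little. Named genes were picked among called probe sets, all of which had groups that did not overlap. Leaving out an array, another offset or the block could therefore not reverse them. Of all calls in sicy-192 against wild type, 74.4% were kept with quantile normalization, 69.6% after centring on the median and 72.3% without the filter. For the double mutant against sicy-192 these shares were 96.4%, 95.3% and 72.7%. Deviations from the group means of arrays with the same replicate number correlated at 0.436, 0.329 and 0.374, but 2 numbers are too few to take them as pairs. The planned analysis has no block, and the higher counts with the block had been seen when the numbers were judged too few. The replicate number as a block gave 5412 changed probe sets for sicy-192 against wild type, 4917 for the double mutant against sicy-192 and 1979 changed back. A threshold of 0.10 gave 1652 changed back. With 1 array left out, the lone array is assumed to vary like the other groups. The changed probe sets then ranged from 2043 to 2968 (sicy-192 against wild type), 1457 to 3262 (double mutant against sicy-192) and 2307 to 4322 (double mutant against wild type), and those changed back from 568 to 956. Probe sets at least 2-fold apart in every pairing ranged from 724 to 1153, 648 to 1048 and 802 to 1306, since fewer pairings have to pass.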

Other observations

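No test in this part was chosen after its result was seen, but which genes and lists to describe here was. All 4 tested photorespiration genes fell in sicy-192, led by the hydroxypyruvate reductase HPR (15842 ± 4821 in wild type to 3783 ± 1573, SD, n = 2 each; log2 change -2.09, adjusted p = 0.00117), and HPR (13842 ± 2451, 1.92) and AT1G32470 (1.02) rose in the double mutant. The nuclear NDH subunit genes NdhL (-2.0, then 0.90) and NdhN (-1.60, then 1.08) fell in sicy-192 and rose in the double mutant, while all 9 plastid-encoded NDH genes fell in that second step. The thylakoid ascorbate peroxidase TAPX fell in sicy-192 (3152 ± 779 to 637 ± 86.5, log2 change -2.26). Its rise in the double mutant (0.64) was no longer called without any 1 of the 4 arrays compared (adjusted p up to 0.172). The zinc finger gene STZ rose from sicy-192 to the double mutant (70.2 ± 4.06 to 401 ± 76.5, log2 change 2.26, adjusted p = 0.00836), a call lost without double mutant replicate 2 (adjusted p = 0.0621). The clock gene GI rose by 1.05.

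Both tested glucosinolate genes fell in the double mutant against sicy-192, BCAT4 (-1.89) and UGT74B1 (-1.22). Without double mutant replicate 2 both calls were lost (adjusted p = 0.115 and 0.0619), and that of BCAT4 also without sicy-192 replicate 1 (0.0881) and without the filter (0.0531). Of 8 tau glutathione transferase genes, GSTU25 (34.4 ± 6.94 to 281 ± 8.13, log2 change 2.57) and GSTU16 (1.98) rose in that step and GSTU20 (-1.37) and GSTU27 (-1.02) fell, and the list was not called (camera adjusted p = 0.632). The call of GSTU27 was lost without sicy-192 replicate 1 (adjusted p = 0.0605) and without double mutant replicate 2 (0.0753). Of 6 tested mitochondrion-encoded genes, nad4 (0.78), ccb452 (1.29) and cox1 (0.98) were called higher in sicy-192 than in wild type, and the list was not called (camera adjusted p = 0.0697). Each of the 3 calls was lost without at least 1 array (adjusted p up to 0.0891 for nad4, 0.0503 for ccb452 and 0.194 for cox1), and that of cox1 also with quantile normalization (0.0668) and after centring on the median (0.0736). None was called from sicy-192 to the double mutant in limma (camera adjusted p = 0.632, fry adjusted p = 0.85). The sugar transporter gene SWEET2 fell in sicy-192 (-1.05) and rose in the double mutant (1.68), and SAG101 did the reverse (1.07, then -1.11). PYK10, a marker of root tissue, was not called in sicy-192 (-0.07) or the double mutant against it (-0.08).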
